A study of Homo sapiens with 82 samples.

How the data were processed

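Bulk RNA was sequenced from 82 libraries of the human induced pluripotent stem cell line KOLF2.2J and of clones derived from it, all collected at day 6 of differentiation towards the trophoblast lineage. The libraries form 7 experiments, each built on 1 transcription factor or cofactor gene. In 3 experiments (MEIS1, MEIS2, MEF2C) the cells followed the scheme that the labels call ExM, which favours extra-embryonic mesenchymal cells. In the other 4 (MXD1, RUNX1, NCOA3, BHLHE40) they followed the scheme called PrS, which favours primitive syncytium. Each experiment held 3 wild-type libraries and knockout libraries made by 3 engineering strategies: deletion labelled as of the full coding length (full), deletion of 1 critical exon (exon) and insertion of a premature stop codon (stop). Per the labels, RNA was isolated with the PicoPure kit, libraries were made with the KAPA RNA HyperPrep kit after ribosomal RNA depletion, and sequencing was done on a NovaSeq X.

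Per the submitters' processing notes, reads were processed with STAR, Salmon and featureCounts against GRCh38, with versions not given in the sources used here. The deposited featureCounts table holds raw counts per gene with no normalization, and these counts were used for every comparison. The deposited Salmon table holds estimated counts per gene and was used only as an alternative, after rounding to whole numbers. A deposited table of read classes gives counts of unmapped, multimapping, unassigned and ambiguous reads per library, and was used to describe the libraries. The count table held 38592 genes, of which 38568 had a symbol in the table or the annotation. GENCODE v29 gave a position for 34390 genes, which carried 99.65% of the counts.

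Libraries were grouped by the labels alone. Assigned counts ran from 17344011 to 39467144 per library (median 24009308), so a gene with no reads can still hold up to 3 counts of a library's total. Limits of this kind cover counting error only. In all 81 pairs of replicates the counts differed (0 identical pairs), by 2.66 to 190.15 times what counting error alone gives (chi-square per gene).

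Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with default settings, a group-means design over all groups, and the quasi-likelihood F test. The single MEIS2 full-deletion library had no replicate. It stood in the fit as a group of its own and entered no contrast, and the filter therefore took 1 library as the smallest group of that experiment. The contrasts were the mean of the 3 strategies against wild type (the exon and stop groups for MEIS2), each strategy against wild type, and a joint test of whether the strategies differ. Calls used a Benjamini-Hochberg adjusted p of 0.05 over all genes tested in that contrast. Standard errors (SE) were derived from the fold change and its F statistic. Levels are TMM-normalised CPM, given as mean ± SD over libraries, and fold changes are log2 values ± SE, knockout over wild type. Wild-type cells of both schemes were compared with the experiment as the replicate (counts summed over the 3 wild-type libraries, 4 PrS against 3 ExM experiments), since the labels do not say whether the libraries of 1 experiment were separate differentiations. Sets of 200 genes changed by 1.5, 2 or 4 times were planted into simulated counts of each comparison, and the share recovered was recorded.

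A total of 30 gene lists (655 genes, all matched) were written before the data were examined, as were the alternatives named here and the rule for naming genes, unless a test is said to have been chosen later. The lists were markers of cytotrophoblast progenitors, syncytiotrophoblast, extravillous trophoblast, mesenchyme, amnion, endoderm, endothelium and blood, cardiac and smooth muscle, neural ectoderm and pluripotency, the HOX genes, targets of TGF-beta and BMP, of WNT and of p53, genes of hypoxia and glycolysis, the integrated stress response, the interferon response, immediate-early genes, the cell cycle, replication-dependent histones, MYC targets of ribosome biogenesis, cholesterol synthesis, the circadian clock, mitochondrially encoded genes, and the families of MEIS, MEF2, MXD1 with MAX, RUNX, NCOA and BHLHE40. The MEF2 family list held fewer than the 5 members required and was reported gene by gene. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 196 list tests of the knockouts and over the 29 lists of the wild types. Camera with a correlation estimated from the data, and fry, were run as alternatives. The preset value treats the members of a list as nearly independent.

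Genes were named by this rule: the targeted gene in every group; the 7 largest rises and the 7 largest falls among called protein-coding genes with a mean of at least 5 CPM whose knockout libraries all lay on 1 side of the wild-type mean; the 3 called members with the smallest p in each called list; the 5 genes with the smallest p in each test between strategies; and the family of the targeted gene. Between wild types the expression minimum was 50 CPM in the higher scheme. XIST and genes of the Y chromosome were never named. A gene outside this rule is said to have been chosen after its values were seen.

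Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, Salmon estimates, a fit of only the 2 groups compared, and each library left out in turn. Further ones were fry, the estimated correlation, a threshold of 0.01 for the overlap of calls, a distance of 100 kb for neighbouring genes, and the MEIS2 full library averaged in. For the wild types, all 21 libraries were also taken as samples, with and without the replicate number as a block. Agreement between strategies was compared with 20 simulations that shared the 3 wild-type libraries but no knockout effect. Up to 60 other splits of the libraries were fitted for each comparison. Neighbours were genes within 500 kb of an altered locus, compared with other genes by Fisher's exact test (two-sided). Tables and exact tests used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.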

Results

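In all, 82 libraries of day 6 in 28 groups were analysed, 61 from knockout clones and 21 from unedited KOLF2.2J cells. Wild-type labels name no clone, so effects of gene loss cannot be told from those of editing and cloning. The ExM scheme (modelling fibroblasts of the villous mesenchyme) held the MEIS1, MEIS2 and MEF2C experiments, and the PrS scheme (modelling primitive syncytium, the early fused trophoblast) the MXD1, RUNX1, NCOA3 and BHLHE40 ones. The series text speaks of 87 samples, and the remainder were not analysed here. Groups held 3 libraries, the MEIS2 full deletion 1. Assigned counts per library lay between 18071034 and 27361805 for MEIS1, 20649854 and 31169567 for MEIS2, 19600500 and 32869559 for MEF2C, and 17344011 and 23758494 for MXD1. They lay between 20581725 and 39467144 for RUNX1, 19336824 and 28640531 for NCOA3, and 19021226 and 30400207 for BHLHE40. The series text calls the libraries biological replicates, but the labels do not say whether wild-type libraries of 1 experiment were separate differentiations, so p-values measure only the spread between libraries. Multimapping reads made up 9.928% and 11.925% of reads in MXD1 full libraries 1 and 2 (5.491% to 7.036% in the other MXD1 libraries), and 22.752% and 26.683% in BHLHE40 stop libraries 1 and 2 (6.523% to 9.388% in the others). MEIS1 wild-type library 1 came from lane 2 while the other MEIS1 libraries came from lane 1, and 8.439% of its reads multimapped against 4.01% to 5.364% in those.

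The level of each targeted gene was compared first, since it checks the labels. Full deletion left 1.59 ± 0.38 CPM of BHLHE40 (ENSG00000134107, chromosome 3, 4979116 to 4985323) against 161 ± 14.2 in wild type, a log2 change of -6.65 ± 0.18 (edgeR adjusted p = 1.24e-14), and 2.52 ± 0.71 CPM of MXD1 (ENSG00000059728, chromosome 2, 69897688 to 69942945) against 212 ± 9.59, a change of -6.38 ± 0.36 (adjusted p = 1.72e-06). RUNX1 (ENSG00000159216, chromosome 21, 34787801 to 36004667) fell to 28.6 ± 2.95 from 86.1 ± 2.07 CPM after full deletion (-1.59 ± 0.13, adjusted p = 1.45e-05). NCOA3 (ENSG00000124151, chromosome 20, 47501902 to 47656877) fell to 493 ± 71.2 from 1368 ± 76.6 CPM (-1.47 ± 0.12, adjusted p = 0.000155). The exon deletion lowered NCOA3 to 520 ± 88.2 CPM (-1.40 ± 0.12, adjusted p = 0.000587) and MEIS2 (ENSG00000134138, chromosome 15, 36889204 to 37101299) to 8.49 ± 0.38 from 17.1 ± 0.86 CPM (-1.01 ± 0.09, adjusted p = 8.78e-05). The premature stop lowered MEIS2 to 8.18 ± 0.86 CPM (-1.06 ± 0.09, adjusted p = 2.19e-05) and BHLHE40 to 104 ± 22.8 CPM (-0.63 ± 0.12, adjusted p = 0.00185). Exon deletion raised the counts of 2 targets, RUNX1 to 137 ± 20.04 CPM (0.67 ± 0.12, adjusted p = 0.00207) and BHLHE40 to 231 ± 17.4 CPM (0.52 ± 0.12, adjusted p = 0.0116). The BHLHE40 rise no longer passed without exon library 2 (adjusted p = 0.059) or wild-type library 2 (adjusted p = 0.0719). The single library labelled MEIS2 full deletion held 23.7 CPM of MEIS2, above the 3 wild-type libraries (16.31 to 18.02 CPM), so its label was not borne out by the count.

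Several targets had lower means without passing the edgeR test (n = 3 libraries per group). MEIS1 (ENSG00000143995, chromosome 2, 66433452 to 66573869) stood at 6.70 ± 0.90, 3.89 ± 1.29 and 2.96 ± 0.51 CPM in full, exon and stop libraries against 11.9 ± 6.49 in wild type (adjusted p = 0.544, 0.622 and 0.367), where wild-type library 1 held 19.3 CPM and the others 9.14 and 7.26. MEF2C (ENSG00000081189, chromosome 5, 88717117 to 88904257) stood at 0.96 ± 0.51, 4.75 ± 3.47 and 7.23 ± 2.30 CPM against 15.6 ± 3.13 (adjusted p = 0.414, 0.553 and 1.0). MXD1 stood at 68.8 ± 20.3 CPM in exon and 67.8 ± 28.4 in stop libraries (adjusted p = 0.183 and 0.0828), NCOA3 at 923 ± 51.5 in stop libraries (adjusted p = 0.428), and RUNX1 at 77.8 ± 12.5 in stop libraries (adjusted p = 0.39). DESeq2 called 6 of these, namely MEIS1 exon (-1.61, adjusted p = 0.00348) and stop (-2.02, 2.54e-05), MEF2C full (-4.02, 1.1e-09), MXD1 exon (-1.63, 2.79e-05) and stop (-1.64, 1.5e-05), and NCOA3 stop (-0.56, 0.0231). Without MXD1 stop library 1 the MXD1 stop change also passed in edgeR (-2.01, adjusted p = 0.0252). Counts over a whole gene check the exon and stop labels only in part, because a transcript that lacks 1 exon or carries a stop still gives reads. By GENCODE v29 (GRCh38) the full deletions covered from 17.3% (MXD1) to 55.2% (BHLHE40) of the exonic bases of their gene. Of the coding bases of all its transcripts they covered 41.6% in RUNX1, 46.8% in MEIS2, 50.2% in MEIS1, 74.7% in MEF2C and 93.8% or more in the others. All labelled loci lay in the coding sequence of the targeted gene except the NCOA3 stop, whose label (chromosome 20, 42625431 to 42625433) lies outside NCOA3.

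**Figure D1:**
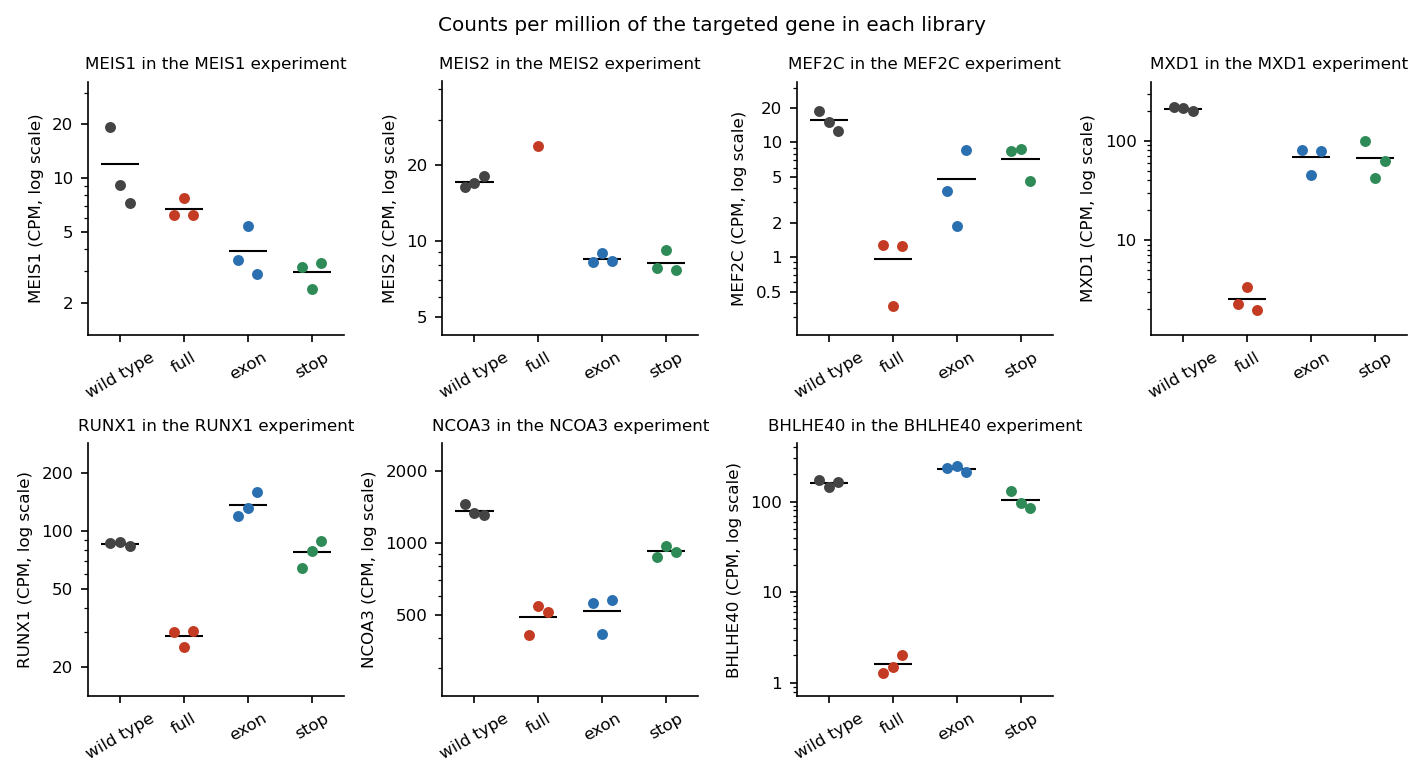
Level of the targeted gene in every library (CPM, logarithmic axis) by group, with lines at group means. Full deletions of BHLHE40 and MXD1 sit near 2 CPM, the RUNX1 and BHLHE40 exon deletions lie above wild type, and the single MEIS2 full library lies above the 3 wild-type libraries.

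Wild-type cells were compared between schemes to describe what each differentiation had made. Most genes that passed in the syncytiotrophoblast and cytotrophoblast progenitor lists were higher in PrS cells, and most in the mesenchyme list in ExM cells. PAGE4, a placenta-expressed gene, stood at 51.0 CPM in PrS and 2.20 in ExM experiments (4.53 log2 units higher, edgeR adjusted p = 0.00759, n = 4 against 3 experiments). DIO3, the placental deiodinase, was 4.43 units higher (adjusted p = 0.00119). PEG10, an imprinted gene needed for the placenta, stood at 1827 ± 1155 against 159 CPM (3.53, adjusted p = 0.00117). The glucose transporter SLC2A1 stood at 2281 ± 417 against 397 ± 86.2 CPM (2.52, adjusted p = 0.000174), and CCR7 at 445 ± 40.2 against 20.1 ± 21.8 CPM (4.47 ± 1.20, adjusted p = 0.0146). Other large PrS genes were LINC00458 (5.82 ± 1.22), MYO7A (4.45), LYPD3 (4.44) and SLC15A2 (4.29). In ExM cells N-cadherin CDH2 reached 448 ± 306 CPM against 0.614 in PrS (-9.49 ± 0.75, adjusted p = 8.63e-05), the filament protein VIM 464 ± 423 against 2.5959 ± 0.9998 CPM (-7.48, adjusted p = 0.000384), and the transcription factor ZEB2 103 against 0.338 CPM (-8.22, adjusted p = 8.47e-05). CDH6 (-10.43 ± 1.46), FLJ16779 (-8.61), OLFML2A (-7.92) and the hyaluronan receptor CD44 (-7.46) were the other large ExM genes. Cardiac actin ACTC1 reached 2000 ± 220 CPM in ExM against 77.5 ± 22.1 in PrS (-4.69, adjusted p = 3.23e-05). The collagen COL5A1 reached 2907 ± 1028 against 183 ± 15.5 (-3.99, adjusted p = 5.26e-05). Of the 7 targeted genes, MXD1 (2.56, adjusted p = 0.00128) and NCOA3 (2.23, 0.00319) were higher in PrS, MEF2C (-3.89, 7.8e-05) and MEIS2 (-1.41, 0.000245) were higher in ExM, and MEIS1 (0.06, 0.903), BHLHE40 (0.33, 0.213) and RUNX1 (-0.60, 0.0676) did not pass.

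Syncytiotrophoblast genes were mostly higher in PrS (27 rose and 2 fell of 42 tested, 33 and 2 adjusted over the list alone), as were cytotrophoblast progenitor genes (20 and 2 of 29, the same counts adjusted over the list alone, camera adjusted p = 1.23e-05 for both). Examples were LHB (2.24), the homeobox genes DLX5 (3.34, 52.6 against 5.17 CPM) and MSX2 (1.67), and CSH2 (5.37, at a low 0.773 against 0.0165 CPM), while PAPPA was lower in PrS (-3.55, 24.04 against 282 CPM, adjusted p = 0.000191). Mesenchyme genes were lower in PrS (4 rose and 21 fell of 34), with SNAI2 at 3.54 against 79.0 CPM, as were cardiac and smooth muscle genes (2 and 14 of 22, MYL7 -3.59, TPM1 -2.65) and TGF-beta and BMP targets (4 and 15 of 21, BAMBI -3.34, SKIL -3.28), each with a camera adjusted p of 9.71e-07. Adjusted over the list alone these were 4 and 21, 3 and 14, and 4 and 15. Genes of the integrated stress response (17 and 2 of 25, adjusted p = 1e-06, HERPUD1 2.49, CHAC1 2.53), MYC targets of ribosome biogenesis (24 and 1 of 31, 6.8e-05, GNL3 1.53, ODC1 2.00, but CCND2 -3.23), the cell cycle (13 and 0 of 31, 0.000607, CDT1 2.06, AURKA 1.41) and replication-dependent histones (13 and 0 of 35, 0.00375, H1-3 1.37) were higher in PrS. Adjusted over the list alone these were 19 and 2, 24 and 1, 12 and 0, and 8 and 0. Cholesterol synthesis (11 and 3 of 24, 0.019, INSIG1 209 against 31.3 CPM, SQLE 705 against 118 CPM), hypoxia and glycolysis (16 and 4 of 29, 0.0435, SLC2A1 2.52, but LOXL2 -4.86 and P4HA2 -2.73) and the NCOA family (3 and 0 of 6, 0.0348, NCOA4 1.97, NCOA2 1.92) were higher too, with 11 and 4, 16 and 4, and 3 and 0 adjusted over the list alone. Targets of p53 (5 and 12 of 23, 0.0348, FAS -4.86, ZMAT3 -2.56, but SESN2 1.07), amnion genes (2 and 6 of 14, 0.0435, ISL1 -4.88, ANKRD1 -6.68), neural ectoderm genes (1 and 4 of 9, 0.0435, NES -6.34, MAP2 -5.49), the MEIS family (1 and 7 of 11, 0.0363, MEIS3 -4.72, PBX3 -1.80) and the RUNX family (0 and 2 of 5, 0.0146, RUNX2 -5.49, RUNX1T1 -3.02) were lower. Adjusted over the list alone these were 5 and 12, 2 and 6, 1 and 4, 1 and 7, and 1 and 4. None of these 17 list calls held in camera with an estimated correlation, where they gave adjusted p = 0.208 to 0.639. Fry called 22 lists, the histones (0.123) not among them.

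The lists not called between the wild types, with their camera adjusted p, were the clock (6 rose and 5 fell of 20, 0.3), extravillous trophoblast (5 and 9 of 21, 0.3), endoderm (4 and 2 of 9, 0.216), endothelium and blood (6 and 4 of 18, 0.68), WNT targets (3 and 6 of 14, 0.26), interferon response (4 and 3 of 22, 0.322), immediate-early genes (10 and 4 of 20, 0.68) and pluripotency (2 and 5 of 13, 0.68). The HOX genes (0 of 5, 0.743), mitochondrially encoded genes (0 of 13, 0.68), the BHLHE40 family (4 and 2 of 7, 0.182) and the MXD1 and MAX family (5 and 1 of 11, 0.109) were not called either. Over all genes, 11469 of 23448 were called (5446 higher in PrS and 6023 higher in ExM). Schemes and library series were partly confounded, so the RUNX1 and MEF2C wild types, both sequenced in lane 3, were compared within that lane (3 against 3 libraries). These p-values take libraries of 1 experiment per scheme as replicates, without replication between experiments. There 13545 genes were called, of which 9425 were also called above, 9420 in the same direction. Within that lane MEIS1 was lower in PrS (-1.30, adjusted p = 1.69e-06) and BHLHE40 higher (0.98, 3.66e-07), while DCX (-2.93 across experiments) and the histone H3C10 (1.43) did not pass (-0.40, adjusted p = 0.409, and 0.14, 0.371).

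Loss of MEIS1, a homeobox factor that acts with PBX and HOX proteins, lowered 7 genes in ExM cells and raised none. Fibrillar collagen COL3A1 fell to 186 ± 27.0 CPM over the 9 knockout libraries from 591 ± 233 in the 3 wild-type libraries (-1.67 ± 0.18, edgeR adjusted p = 0.00965). LRRN4, a leucine-rich repeat membrane protein, fell to 19.7 ± 3.09 from 51.3 ± 5.54 CPM (-1.38 ± 0.13, adjusted p = 0.00405), and SLITRK6, a membrane protein known from neurons, to 67.2 ± 9.88 from 143 ± 30.6 (-1.09 ± 0.13, adjusted p = 0.0211). CRLS1, the cardiolipin synthase gene that lies beside LRRN4 on chromosome 20 (-0.93 ± 0.13), the procollagen protease ADAMTS2 (-0.75 ± 0.10), the GDNF receptor GFRA1 (-0.70 ± 0.10) and EMP1 (-0.54 ± 0.08) fell as well (adjusted p = 0.0456 each). No member of the MEIS family passed, with MEIS2 at -0.31 ± 0.10 (adjusted p = 0.465), PBX1 at -0.45 ± 0.10 (0.211), PBX4 at 0.41 ± 0.19 (0.549), and MEIS3, PBX2, PBX3, PKNOX1, PKNOX2, TGIF1 and TGIF2 between -0.20 and 0.08.

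In the MEIS1 experiment camera called HOX genes lower (adjusted p = 2.87e-11, median -0.74 over 11 genes, 0 called over all genes and 7 lower adjusted over the list alone), which gave adjusted p = 0.158 with an estimated correlation and 0.0154 in fry. It called mesenchyme genes lower (6.13e-05, 1 of 34 fell, 10 lower adjusted over the list alone) and amnion genes lower (8.44e-07, 0 of 13, 7 lower adjusted over the list alone), both with adjusted p = 0.502 with an estimated correlation. Replication-dependent histones (5.19e-11, 30 of 33 lower) and the cell cycle (1.95e-09, 31 of 31 lower) were called lower, with 0 genes called and, adjusted over the list alone, 1 up and 13 down, and 0 up and 8 down (adjusted p = 0.52 and 0.571 with an estimated correlation). Mitochondrially encoded genes (3.02e-07, 13 of 13 higher), the integrated stress response (1.67e-06), cardiac and smooth muscle genes and cholesterol synthesis (0.000754 each) were called higher. So were neural ectoderm (0.0129), MYC targets of ribosome biogenesis (0.0244), pluripotency (0.0391), p53 targets and the interferon response (0.0468 each). These 9 lists held 0 called genes, 1 gene adjusted over the list alone (in the interferon list), and adjusted p = 0.501 to 0.636 with an estimated correlation. The syncytiotrophoblast list was not called, and its mean per library ran from -2.49 (stop library 2) to 1.07 log2 units (wild-type library 1). Without wild-type library 1, an alternative chosen after seeing the data, the HOX (7.57e-21), mesenchyme (6.43e-13) and histone (3.66e-05) calls remained, the cell cycle (0.403), cardiac (0.274), cholesterol (0.068), neural (0.678), p53 (0.854) and pluripotency (0.0781) calls ended, and the syncytiotrophoblast list was called higher (0.000285), and TGF-beta and BMP targets (0.00473) and the MEIS family (0.0423) lower.

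Over all 19795 genes of the MEIS1 experiment the 3 strategies together gave these 7 calls with edgeR (1798 genes at an unadjusted p under 0.05, and 95 calls with DESeq2, 11 higher and 84 lower). Singly, full, exon and stop gave 0 calls (1730, 855 and 1577 genes at an unadjusted p under 0.05, and 64, 24 and 39 with DESeq2). The strategies did not differ for any gene (0 calls, 524 at an unadjusted p under 0.05, 1 with DESeq2). The genes with the smallest p there were ZNF736, H4C4, NCK1-DT, SULF1 and ZNF432 (adjusted p = 0.992 each, as for MEIS1 itself). The count of 7 became 2 without full library 3, exon library 1 or 3, stop library 1 or wild-type library 2, 3 without full library 2, 4 without exon library 2, stop library 3 or wild-type library 1, and 14 without wild-type library 3. The exon count became 2 without wild-type library 1, the stop count 1 without stop library 1, and the count of genes that differ 1 without exon library 2. At this spread 64.2% of planted 2-fold and 31.3% of 1.5-fold changes were recovered, shares that may be too high where few genes change.

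Loss of MEIS2, a close relative of MEIS1, by exon deletion or premature stop lowered COL3A1, COL6A3 and LUM in ExM cells. COL3A1 fell to 339 ± 32.2 from 519 ± 27.7 CPM (-0.62 ± 0.05, edgeR adjusted p = 5.46e-06, n = 6 against 3), the microfibrillar collagen COL6A3 to 7.82 ± 3.46 from 15.7 ± 3.07 (-1.09 ± 0.21, 0.0366), the proteoglycan LUM to 139 ± 23.8 from 205 ± 10.8 (-0.56 ± 0.10, 0.0303) and the mesenchymal cadherin CDH11 by 0.30 log2 units (0.0288). LRRN4 fell to 20.9 ± 5.16 from 43.6 ± 1.43 CPM (-1.08 ± 0.09, adjusted p = 2.62e-05). CTNNA3 (-0.92), the neurotrophin receptor NTRK2 (-0.80), CNTNAP2 (-0.75) and ELAPOR2 (-0.75) fell too, as did the cardiac regulators MYOCD (-0.55) and ISL1 (-0.36). The genes that rose most were the hemidesmosome collagen COL17A1 (0.82 ± 0.16, 14.23 ± 4.36 against 8.005 ± 1.10 CPM), the pyrimidine-degrading enzyme DPYD (0.63), the natriuretic peptide NPPB (0.61 ± 0.11, 171 ± 39.7 against 111 ± 10.4 CPM), PRUNE2 (0.57), TMEM40 (0.47), SIM2 (0.43) and NEK10 (0.40). The aromatase gene CYP19A1, a syncytiotrophoblast marker, fell by 3.76 ± 0.75 (adjusted p = 0.0421), a call that rested on high counts in wild-type library 2 (wild-type mean 4.73 ± 6.09 CPM). Each of these genes passed in stop clones alone, but in exon clones alone only COL3A1, LRRN4 and ELAPOR2 did (COL6A3 at -0.62, adjusted p = 0.503, LUM 0.263, CDH11 0.438). None was called as different between strategies. Family members did not pass, with MEIS1 at -0.29 ± 0.11 (0.361), PBX1 at -0.28 ± 0.08 (0.159) and MEIS3, PBX2, PBX3, PBX4, PKNOX1, PKNOX2, TGIF1 and TGIF2 between -0.27 and 0.03.

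In the MEIS2 experiment camera called mesenchyme genes lower (adjusted p = 5.81e-12, 28 of 33 lower, 5 fell, 8 adjusted over the list alone), with adjusted p = 0.501 with an estimated correlation. Syncytiotrophoblast (5.31e-07, 1 of 35 fell, 1 up and 14 down adjusted over the list alone), HOX (4.97e-06, 0 of 12, 3 down), amnion (0.000519, 1 of 12 fell, 5 down), replication-dependent histone (0.000408, 0 and 0), WNT target (0.0296, 1 down), MEIS family (0.0119, 1 down) and RUNX family genes (0.0391, 1 down) were called lower. Their adjusted p was 0.501 to 0.636 with an estimated correlation. The syncytiotrophoblast list mean was 0.6341 in wild-type library 2, while wild-type libraries 1 and 3 (-0.2448 and -0.3893) lay near or among the exon and stop libraries (-0.4655 to -0.2876). Called higher were cholesterol synthesis (3.02e-07, 0 of 24 called, 6 up adjusted over the list alone), the integrated stress response (8.01e-07, 1 of 25 rose, 6 up, with the folate enzyme ALDH1L2 at 0.30), mitochondrially encoded genes (2.16e-06, 13 of 13 higher, 1 up), cardiac and smooth muscle genes (0.000603, 1 rose and 1 fell of 22, 7 up and 1 down), hypoxia and glycolysis (0.0156, 0) and MYC targets of ribosome biogenesis (0.032, 0). They gave adjusted p = 0.564 to 0.619 with an estimated correlation.

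Over 20058 genes the MEIS2 exon and stop clones together gave 75 calls (21 higher and 54 lower), the stop clones alone 264 (124 and 140) and the exon clones alone 10 (1 and 9). Of 5 genes whose change differed between both strategies (adjusted p = 0.035 each), CYSLTR2, a leukotriene receptor, stood at 19.4 CPM in exon and 12.6 in stop against 25.3 in wild-type libraries. S100A6 stood at 0.15 in exon and -0.23 in stop, DIPK2A at -0.16 and 0.38, ARGLU1 at -0.18 and 0.19, and ZNF431 at -0.21 and 0.19. MEIS2 itself was not called as different (0.876). The joint count became 36 and 35 without exon library 1 or 3, 239, 22 and 280 without stop library 1, 2 or 3, and 15, 17 and 14 without wild-type library 1, 2 or 3. The exon count became 5 and 6 without exon library 1 or 3, and 5, 6 and 2 without wild-type library 1, 2 or 3. The stop count became 48 and 797 without stop library 2 or 3, and 40, 125 and 22 without wild-type library 1, 2 or 3. The count of genes that differ became 27, 0 and 0 without exon library 1, 2 or 3, and 278, 0 and 455 without stop library 1, 2 or 3.

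MEIS1 and MEIS2 loss shared 5 falling genes, COL3A1, LRRN4, CRLS1, ADAMTS2 and SLITRK6, where 0.0196 would be shared if calls were independent. In the MEIS2 experiment CRLS1 fell by 0.67 ± 0.07, ADAMTS2 by 0.50 ± 0.10 and SLITRK6 by 0.42 ± 0.05. None of the 5 passed in the MEF2C experiment (between -0.09 and -0.01, adjusted p = 0.999 each), although MEF2C wild-type cells held 121.87 CPM of COL3A1 and 47.8 of LRRN4.

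Loss of MEF2C, a MADS-box factor of muscle and mesenchyme, gave no called gene in ExM cells. MEF2C itself stood at -2.29 ± 0.37 over the 3 strategies (edgeR adjusted p = 0.999), and its relatives did not pass either, namely MEF2A (-0.15 ± 0.20), MEF2B (0.16 ± 0.27) and MEF2D (-0.01 ± 0.18, all 0.999). Camera called 10 lists. Mitochondrially encoded genes were lower (adjusted p = 2.64e-14, 13 of 13 lower, median -0.37), with adjusted p = 0.501 with an estimated correlation. Higher were replication-dependent histones (4.39e-10, 33 of 33 higher), the integrated stress response (7.84e-07, 24 of 25), MYC targets of ribosome biogenesis (0.00018, 28 of 31), cholesterol synthesis (0.01, 19 of 23), cytotrophoblast progenitor (0.0156, 24 of 28), syncytiotrophoblast (0.0157, 36 of 40), hypoxia and glycolysis (0.018, 19 of 28), cell cycle (0.0209, 22 of 31) and immediate-early genes (0.0391, 14 of 19). They gave adjusted p = 0.502 to 0.771 with an estimated correlation. None of the 10 held a called gene, over all genes or adjusted over the list alone. The syncytiotrophoblast mean per library ran from -0.74 (full library 3) to 1.36 log2 units (exon library 2). Median and test differed in sign for the mesenchyme, cardiac and WNT lists, none of which was called.

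Of 20628 genes in the MEF2C experiment, edgeR called 0 over the 3 strategies (807 at an unadjusted p under 0.05, 1 call with DESeq2), 0 in full (736, 2 with DESeq2), 0 in exon (1673), 0 in stop (264) and 0 that differed between strategies (559, 4 with DESeq2). A fit of only the full and wild-type groups called 2. The smallest p between strategies belonged to ENSG00000289195, MEF2C, MAPK4, PLCG2 and RGP1 (adjusted p = 0.716 each). At this experiment's spread 46.3% of planted 2-fold and 6% of 1.5-fold changes were recovered. These shares may be too high with few genes changed, and MEF2C itself was not called.

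**Figure D2:**
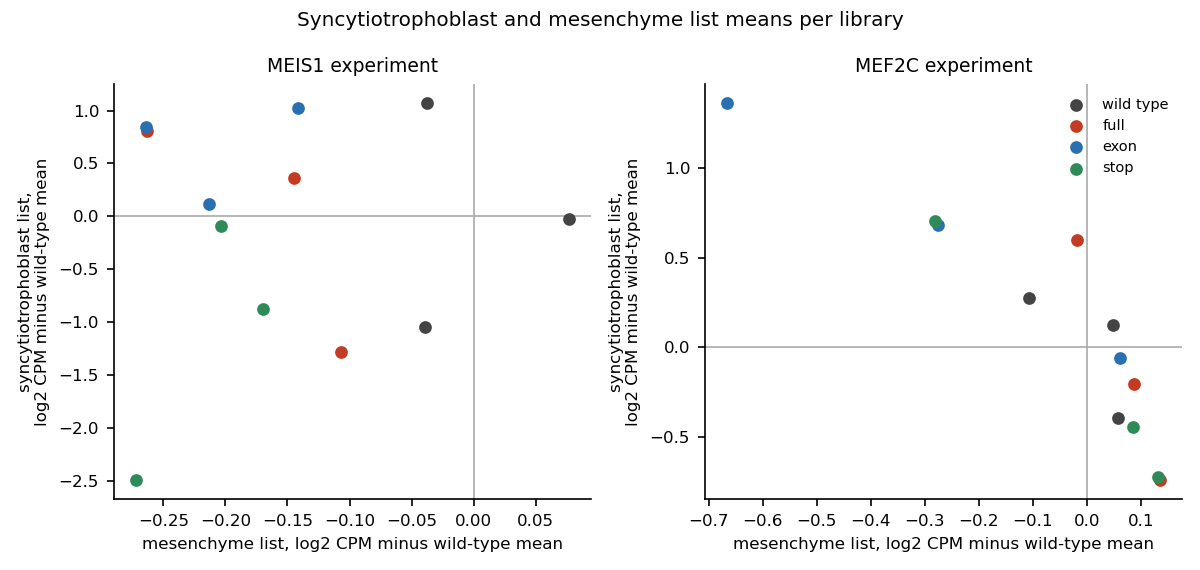
Mean of the syncytiotrophoblast list against mean of the mesenchyme list in each library (log2 units relative to wild type) of the MEIS1 and MEF2C experiments, coloured by group. The syncytiotrophoblast mean spans -2.49 to 1.07 in MEIS1 and -0.74 to 1.36 in MEF2C libraries.

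Loss of MXD1, a repressor that competes with MYC for MAX, raised genes of ribosome biogenesis in PrS cells. RRP12, a factor of pre-ribosome export, rose to 187 ± 34.8 CPM over 9 knockout libraries from 66.0 ± 5.53 in 3 wild-type libraries (1.49 ± 0.13, edgeR adjusted p = 0.000216). Other factors that make ribosomal subunits rose with it, namely NOL6 (1.10 ± 0.13, 74.5 ± 10.9 against 34.6 ± 4.28 CPM, 0.00625), UTP20 (1.05 ± 0.15, 0.0254), DHX37 (0.95 ± 0.13, 0.0156), MAK16 (0.82 ± 0.10, 0.00625) and RRS1 (0.62 ± 0.10, 0.046). The diphthamide gene DPH2 (0.81) and the valyl-tRNA synthetase VARS1 (0.81) rose too. TAF5L fell to 97.2 ± 8.26 from 136 ± 5.97 CPM (-0.48 ± 0.08, 0.0484). In the fixed list of MYC targets of ribosome biogenesis 30 of 31 genes were higher (median 0.37, camera adjusted p = 5.6e-32), 2 were called over all genes and 23 adjusted over the list alone, with adjusted p = 0.494 with an estimated correlation. The list mean of each knockout library (0.11 to 0.72) lay above those of the wild-type libraries (-0.01 to 0.02). No family member passed, with MAX at 0.35 ± 0.08 (0.201), MYCN at -0.48 ± 0.11 (0.208), MYC at 0.02 ± 0.13 (0.983), and MXD3, MXD4, MXI1, MNT, MGA, MYCL and MLX between -0.21 and 0.19.

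Camera called 8 other lists in the MXD1 experiment, none with a gene called over all genes. Syncytiotrophoblast (7.38e-07, 31 of 41 lower), cytotrophoblast progenitor (8.15e-05, 21 of 29 lower), hypoxia and glycolysis (0.000266, 26 of 28 lower), extravillous trophoblast (0.0111, 14 of 21 lower), endothelial and blood (0.0258, 8 of 11 lower) and immediate-early genes (0.0299, 15 of 19 lower) were lower. Targets of p53 (0.00174, 20 of 23 higher) and cardiac and smooth muscle genes (0.00411, 19 of 19 higher) were higher. Adjusted over the list alone, 1 extravillous and 2 endothelial genes were lower and 1 p53 target was higher. These 8 lists gave adjusted p = 0.502 to 0.758 with an estimated correlation. In full libraries 1 and 2 mitochondrially encoded genes took 2.5611% and 2.6075% of the counts against 4.4003% to 6.0618% in the other MXD1 libraries. Without both, an alternative chosen after seeing the data, the ribosome list was still called (8.96e-27), the endothelial and blood (0.137) and immediate-early calls (0.187) ended, and mitochondrially encoded genes were called higher (5.14e-06) and endoderm genes lower (0.0464).

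Of 19621 genes in the MXD1 experiment 19 were called over the strategies (17 higher and 2 lower, MXD1 and TAF5L), 9 in full (8 and 1), 2 in exon (2 and 0) and 5 in stop (5 and 0). DESeq2 called 120, 199, 61 and 64. Only MXD1 itself differed between strategies (adjusted p = 0.000105), and TMUB1, COL5A1, AAMP and MT-ATP8 followed (0.37 each). The joint count became 8, 6 and 30 without full library 1, 2 or 3, 6 without exon library 3, 8, 7 and 5 without stop library 1, 2 or 3, and 4, 2 and 2 without wild-type library 1, 2 or 3. The full count became 2, 2 and 1076 without full library 1, 2 or 3, and 3, 2 and 2 without wild-type library 1, 2 or 3. The exon count became 5, 1 and 0 without exon library 1, 2 or 3 and 0 without any 1 wild-type library. The stop count became 1 and 2 without stop library 2 or 3, and 0, 0 and 1 without wild-type library 1, 2 or 3. The count of genes that differ became 1027 without full library 3 and 2 without exon library 1.

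**Figure D3:**
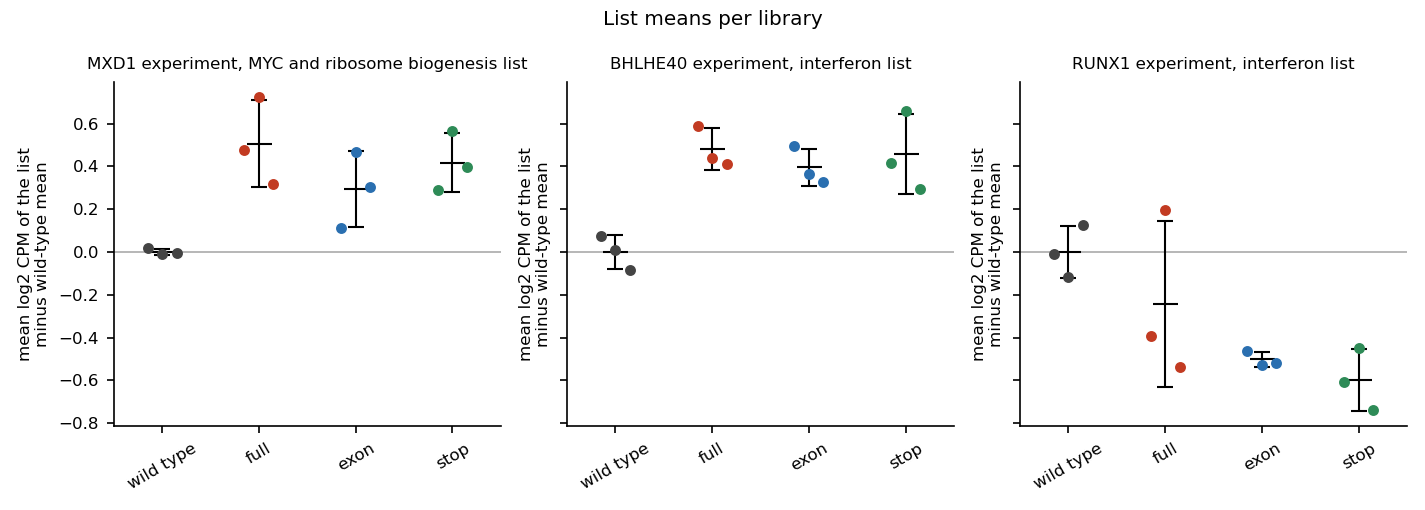
Mean log2 level of list members per library relative to wild type, for ribosome biogenesis in the MXD1 experiment and the interferon response in the BHLHE40 and RUNX1 experiments (points, libraries; bars, mean ± SD, n = 3). All 9 MXD1 and all 9 BHLHE40 knockout libraries lie above their wild types, and 8 of 9 RUNX1 knockout libraries lie below theirs, RUNX1 full library 2 (0.195) being above.

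Loss of RUNX1, a runt-domain factor of blood and epithelia, gave the most calls over the strategies (4761, then 1937 for BHLHE40). It did not for full deletion alone (447 against 1154), nor with a library score, chosen after seeing the data, as a covariate (59 against 1239). In PrS cells leptin LEP rose, at 30.4 ± 10.4 against 6.99 ± 1.37 CPM (2.08 ± 0.31, edgeR adjusted p = 0.000602, n = 9 against 3), as did the protease PAPPA2 at 119 ± 72.5 against 26.4 ± 4.53 (2.08 ± 0.38, 0.00186), corticotropin-releasing hormone CRH at 14.8 ± 3.62 against 5.37 ± 1.85 (1.46 ± 0.22, 0.000668) and IGFBP5 at 81.1 ± 71.6 against 10.6 ± 2.77 (2.75 ± 0.61, 0.00563). CDX2, an early trophoblast factor, rose at a low level (2.50 ± 0.63 against 0.47 ± 0.12 CPM, 2.39 ± 0.27, 0.000113), as did SLIT3 (2.36), MXRA5 (2.07), KLRD1 (2.00) and CDH10 (1.97). The tropomyosin TPM2 fell, at 34.4 ± 20.8 against 74.3 ± 14.8 CPM (-1.22 ± 0.20, 0.00112), as did myosin light chain MYL9 at 30.96 ± 17.96 against 65.8 ± 13.9 (-1.16 ± 0.22, 0.00229) and tissue factor F3 at 4.81 ± 3.10 against 13.2 ± 3.75 (-1.58 ± 0.22, 0.00034). SH3RF2 (-1.60), ALS2CL (-1.49), ENTREP1 (-1.42), NCKAP5L (-1.24) and the integrin ITGB8 (-1.24) fell too. CROCCP2 (-2.68) fell from a wild-type mean that varied widely (70.5 ± 94.4 CPM). Of its family RUNX3 rose (1.23 ± 0.39, 0.0324), RUNX2 fell (-0.88 ± 0.30, 0.0455), and CBFB (0.20 ± 0.07, 0.0521) and RUNX1T1 (0.53 ± 0.32, 0.236) did not pass. LEP, IGFBP5, CDH10, TPM2, MYL9, F3 and SH3RF2 are among the genes of largest weight in that score from the MXD1 and NCOA3 experiments. Full library 2 (22.012) lay above the wild types on it (7.593 to 18.365) and the other knockouts below (-14.863 to 3.513).

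Camera called 13 lists in the RUNX1 experiment. Higher were the integrated stress response (adjusted p = 3.02e-07, 16 rose and 1 fell of 25), with the cystine transporter SLC7A11 at 92.0 ± 37.4 against 38.2 ± 5.79 CPM and the regulator ATF4 (0.54), and hypoxia and glycolysis (6.08e-06, 12 and 0 of 28), with the oxygen sensor EGLN3 (1.64), glucose transporter SLC2A3 (1.05) and PFKFB3 (0.73). Extravillous trophoblast (6.13e-05, 11 and 2 of 21, FN1 0.52, EBI3 2.00), immediate-early (0.00025, 10 and 1 of 20, KLF10 0.91, EGR1 0.81, with FOSB at -0.48), WNT target (0.00954, 5 and 0 of 12, ZNRF3 0.49, NKD2 0.83, LEF1 0.86), syncytiotrophoblast (0.0129, 13 and 6 of 40, SLC40A1 0.82), cytotrophoblast progenitor (0.0173, 11 and 5 of 29, EGFR 0.89, SPINT1 0.59), endoderm (0.018, 4 and 0 of 7, GATA6 0.52, TTR 0.54, APOA1 1.57) and amnion genes (0.0424, 5 and 0 of 14, ISL1 1.14, TNNC1 0.49) were higher as well. Lower were MYC targets of ribosome biogenesis (8.44e-07, 1 rose and 18 fell of 31, NOLC1 -0.54, CAD -0.61, PPAN -0.51), the cell cycle (1.12e-05, 0 and 10 of 31, MKI67 -0.62, CCNB1 -0.61, MCM2 -0.57), the interferon response (0.000975, 1 and 13 of 21, ISG15 -1.14, OAS1 -1.26, MX1 -0.67) and cardiac and smooth muscle genes (0.0283, 2 and 8 of 20, TPM2 and MYL9 among them, although KLF4 rose). Adjusted over the list alone the counts were 16 and 1, 12 and 0, 14 and 2, 12 and 1, 5 and 0, 15 and 6, 13 and 6, 4 and 0, 5 and 0, 2 and 21, 0 and 13, 1 and 14, and 2 and 8. All 13 lost their call with an estimated correlation (adjusted p = 0.502 to 0.744), and fry called 4 of them, namely ribosome biogenesis (0.0154), WNT (0.022), extravillous (0.0238) and hypoxia (0.0452).

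Of 20019 genes in the RUNX1 experiment 4761 were called over the strategies (2423 higher and 2338 lower), 447 in full (298 and 149), 4322 in exon (2362 and 1960) and 5915 in stop (2972 and 2943). The share of unmapped reads parted the 9 knockout (3.385% to 3.69%) from the 3 wild-type libraries (3.737% to 4.046%). No other read class parted them in any experiment (1 of 35 comparisons, made after seeing the data). The strategies differed for 2289 genes. RUNX1 itself did (adjusted p = 4.91e-07), and so did ENSG00000286153, which fell only after full deletion (-3.51 ± 0.21, with 0.02 in exon and 0.05 in stop). The chemokine CXCL14 stood at 0.35 in full, -1.38 in exon and -1.36 in stop (0.00146), TAF13 at 0.22, -0.57 and -0.36 (0.00193), and the sphingomyelin synthase SGMS2 at 0.02, -1.15 and -0.57 (0.00199). The joint count became 2012 and 1395 without wild-type library 1 or 3. The full count became 25, 2010 and 289 without full library 1, 2 or 3, and 74, 117 and 16 without wild-type library 1, 2 or 3. The exon count became 2654 without exon library 1 and 2299 and 2100 without wild-type library 1 or 3. The stop count became 3254 without stop library 3 and 3247 and 2871 without wild-type library 1 or 3. The count of genes that differ became 718, 458 and 4695 without full library 1, 2 or 3, 1352 without exon library 2 and 1262 without stop library 3.

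Loss of NCOA3, a coactivator of nuclear receptors, went with mostly small changes in PrS cells. The lipoxygenase ALOX15B rose to 7.24 ± 1.24 from 3.32 ± 0.87 CPM (1.11 ± 0.15, edgeR adjusted p = 0.00795, n = 9 against 3), the ribonucleotide reductase subunit RRM2 to 429 ± 48.7 from 289 ± 16.0 (0.56 ± 0.07, 0.00425) and the Notch ligand JAG1 to 97.4 ± 9.56 from 65.9 ± 3.19 (0.56 ± 0.08, 0.00921). SPDYC (0.86), the BMP9 receptor ACVRL1 (0.63), TMEM37 (0.60) and the monocarboxylate transporter SLC16A5 (0.55) rose too. The orphan receptor GPR158 fell to 8.66 ± 2.51 from 16.7 ± 2.79 CPM (-0.97 ± 0.19, 0.0417), osteopontin SPP1 to 14.99 ± 3.27 from 22.8 ± 1.35 (-0.62 ± 0.12, 0.0378) and PRRT1B to 25.6 ± 2.44 from 37.6 ± 1.99 (-0.56 ± 0.07, 0.004), as did the nucleotide transporter SLC17A9 (-0.60), OTOGL (-0.57) and AGFG2 (-0.56). No other coactivator of the family passed, with NCOA2 at -0.08 ± 0.06 (0.638) and NCOA1, NCOA4, NCOA6 and NCOA7 between -0.06 and 0.04. The only list called was ribosome biogenesis, at a median of -0.06 (27 of 31 lower, 0 called over all genes, 1 lower adjusted over the list alone, camera adjusted p = 0.00313, adjusted p = 0.636 with an estimated correlation). ZNF736, a zinc finger gene on chromosome 7, was the gene that differed most between strategies (5.48e-08). It had 0 counts in all 3 full libraries, where up to 3 counts per library (at most 0.137 CPM) would go unseen, against 7.88 ± 1.07 CPM in wild type, and it was at least 50.8-fold lower in each than in the lowest wild-type library (6.9652 CPM).

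Of 18399 genes in the NCOA3 experiment 101 were called over the strategies (31 higher and 70 lower), 92 in full (48 and 44), 73 in exon (15 and 58) and 0 in stop with edgeR (984 at an unadjusted p under 0.05, 21 with DESeq2, 7 with no filter, 4 in a fit of the 2 groups alone). Of these only ZNF736 and NCOA3 (0.038) differed between strategies, and GABRE, IGSF10 and GNG12-AS1 followed (0.583, 0.583 and 0.608). The joint count became 341 and 34 without full library 1 or 3, 60 and 43 without exon library 2 or 3, 36, 38 and 34 without stop library 1, 2 or 3, and 12, 4 and 3 without wild-type library 1, 2 or 3. The full count became 1477, 18 and 5 without full library 1, 2 or 3, and 24, 4 and 4 without wild-type library 1, 2 or 3. The exon count became 36, 1 and 4 without exon library 1, 2 or 3, and 1 without any 1 wild-type library. The count of genes that differ became 442 without full library 1, and 1 without full library 3, exon library 1 or any 1 stop library.

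Loss of BHLHE40, a basic helix-loop-helix repressor of clock and stress genes, lowered INSL4 and chorionic gonadotropin genes and raised genes of the interferon list in PrS cells. The relaxin-family gene INSL4 fell to 29.01 ± 3.43 from 103 ± 8.07 CPM (-1.83 ± 0.08, edgeR adjusted p = 3.08e-11, n = 9 against 3), and the chorionic gonadotropin genes CGB5 to 40.03 ± 10.8 from 165 ± 39.5 (-2.06 ± 0.16, 7.39e-08) and CGB3 to 37.3 ± 9.71 from 116 ± 25.4 (-1.66 ± 0.13, 6.24e-08), although near-identical CGB copies share reads, so the value of each copy is uncertain. The phosphatase PTPRB (-1.75), the proteoglycan ACAN (-1.60), the sodium pump subunit ATP1B1 (-1.60, 98.3 ± 17.6 against 296 ± 48.8 CPM) and the deiodinase DIO3 (-1.55) fell as well. The death ligand FASLG rose to 11.7 ± 1.52 from 0.93 ± 0.23 CPM (3.68 ± 0.18, 2.9e-10), the water channel AQP3 to 111 ± 25.4 from 33.1 ± 4.61 (1.74 ± 0.16, 6.5e-07), and TMEM51 (2.23), RMI2 (1.63), CBX4 (1.57), LY6G6C (1.43) and RTL5 (1.41) rose too. Of its family BHLHE41 rose (0.48 ± 0.10, 0.00348) and HEY1 fell (-0.46 ± 0.10, 0.00513), while HES1 (0.25 ± 0.12, 0.226), HES2 (-0.27 ± 0.09, 0.0656) and HES4 (0.61 ± 0.28, 0.21) did not pass and HEY2 was too low to test.

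Camera called 7 lists in the BHLHE40 experiment. The interferon response was higher (adjusted p = 2.46e-11, 12 rose and 0 fell of 21, 15 and 0 adjusted over the list alone), with the ubiquitin-like ISG15 at 25.1 ± 3.35 against 12.7 ± 1.56 CPM, MX1 (0.85) and OAS3 (1.03), and with adjusted p = 0.501 with an estimated correlation. Syncytiotrophoblast genes were lower (2.94e-10, 2 rose and 11 fell of 39, 3 and 14 adjusted over the list alone), with adjusted p = 0.564 with an estimated correlation. The cell cycle (3.28e-05, 8 rose of 31, 9 adjusted over the list alone, CENPF 0.39, BUB1 0.29, MKI67 0.27), pluripotency (0.00505, 2 of 11, 3, with the DNA methyltransferase DNMT3B at 245 ± 13.5 against 134 ± 1.16 CPM and L1TD1 at 0.33), replication-dependent histones (0.00385, 3 of 35, 3, H1-3 0.36, H1-5 0.28, H2AC13 0.23) and cardiac and smooth muscle genes (0.00787, 5 of 18, 12 up and 2 down, ACTA2 1.06, TAGLN 0.55, KLF4 0.53) were higher. The MXD1 and MAX family was lower (0.0295, 1 rose and 2 fell of 11, 1 and 4), MXD3 (-1.27) and MYCN (-0.36) having fallen and MXD1 risen (0.32). These 5 gave adjusted p = 0.501 to 0.664 with an estimated correlation. Fry called the interferon (0.0211), cell cycle (0.022), pluripotency (0.0154) and MXD1 and MAX family lists (0.0445). Without stop libraries 1 and 2, an alternative chosen after seeing the data, the interferon (4.74e-10) and syncytiotrophoblast (1.44e-13) calls remained, and cytotrophoblast progenitor (0.0131), immediate-early (0.0135) and mitochondrially encoded genes (0.0253) were called lower.

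Of 18961 genes in the BHLHE40 experiment 1937 were called over the strategies (832 higher and 1105 lower), 1154 in full (525 and 629), 1054 in exon (522 and 532) and 1856 in stop (787 and 1069). Of the 5 genes that differed between strategies, BHLHE40 itself came first (1.93e-14). The mitochondrial gene CHCHD2 was lower in stop clones alone (38.0 ± 2.29 against 60.3 ± 4.65 CPM in wild type, 0.00356). ENSG00000281181 (102 ± 99.6 CPM in stop against 0.613 ± 0.52 in wild type, 0.00617), ENSG00000281383 (45.6 ± 39.8 against 1.28 ± 0.46, 0.00718) and ENSG00000278996 (0.025, named after its value was seen) were higher in the stop group, which holds the libraries with the most multimapping reads. ENSG00000280441 did not pass (0.0521). The joint count became 1250 and 1185 without wild-type library 1 or 3. The full count became 661, 709 and 740 without full library 1, 2 or 3, and 746 and 700 without wild-type library 2 or 3. The stop count became 3128 and 992 without stop library 1 or 2, and 1100 and 1184 without wild-type library 1 or 3. The count of genes that differ became 10 without full library 3, 848 and 11 without stop library 1 or 3, and 52 without both stop libraries of high multimapping.

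**Figure D4:**
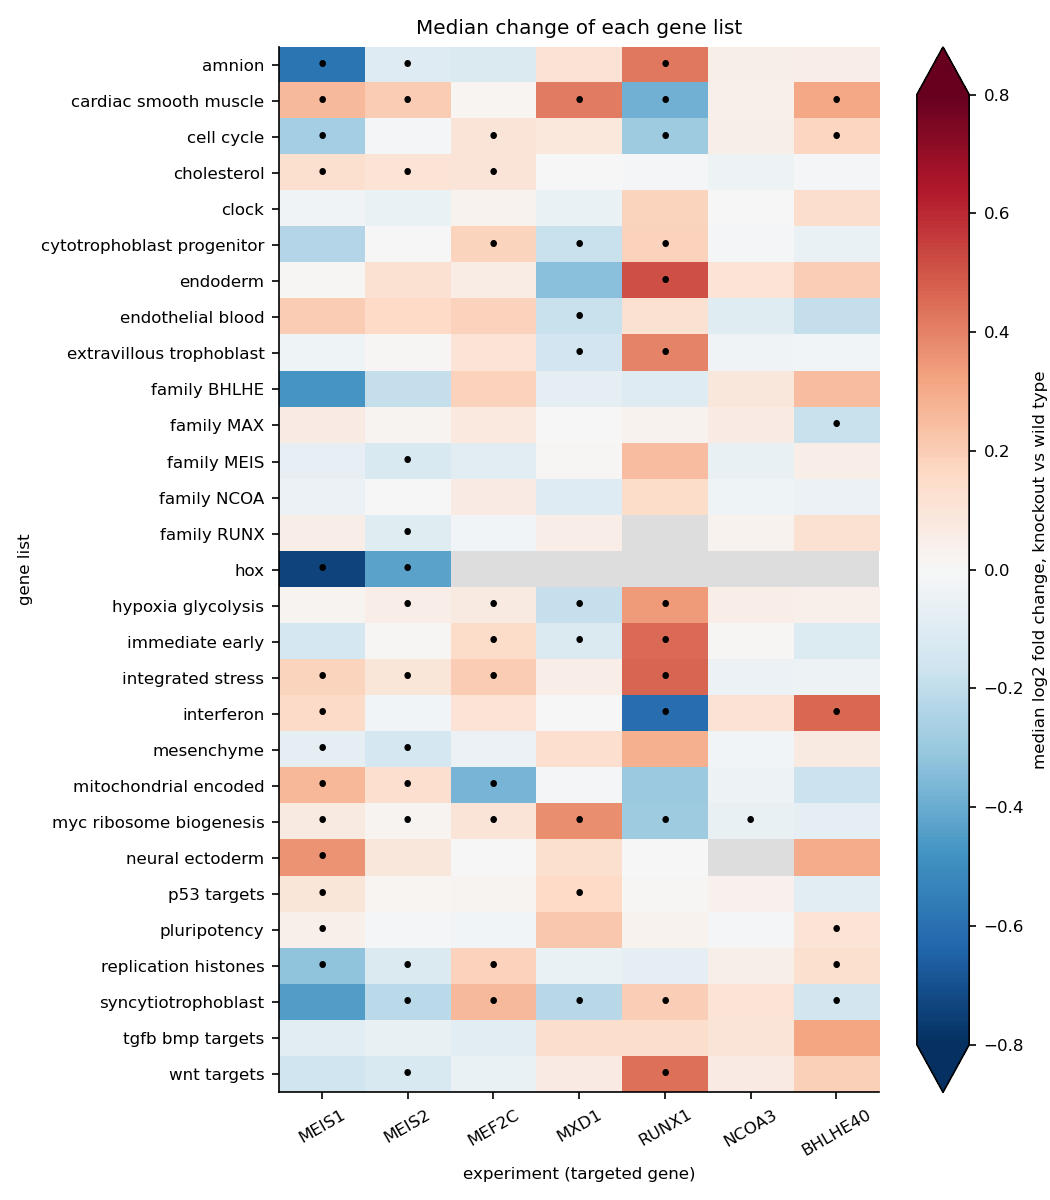
Median log2 fold change of each fixed gene list (vertical axis) in each knockout experiment (horizontal axis), with dots where camera called the list at a preset correlation and grey where fewer than 5 members were tested. Ribosome biogenesis is higher in MXD1 and lower in RUNX1 knockouts, and the interferon list is higher in BHLHE40 and lower in RUNX1 knockouts.

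Of the 196 list tests in knockouts 68 were called, and none with an estimated correlation (smallest adjusted p = 0.158). Lists called in no knockout, with all libraries, were the clock (camera adjusted p between 0.137 and 0.908), TGF-beta and BMP targets (0.0751 to 0.606), the BHLHE40 family (0.0724 to 0.998) and the NCOA family (0.18 to 0.938). In clock genes 2 rose and 1 fell of 18 after loss of BHLHE40.

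The series set out to compare engineering methods, so the fold changes of strategies were compared within each gene. Across genes, exon and stop clones of RUNX1 correlated at r = 0.84, full with exon at 0.63 and full with stop at 0.62. The BHLHE40 strategies gave 0.66, 0.69 and 0.65 (full with exon, full with stop, exon with stop), and the MEIS2 exon and stop clones 0.56. Genes are not independent replicates, and sharing 3 wild-type libraries alone gave 0.48 to 0.52 in simulations without any knockout effect (0.509 for MEIS2). The covariance of exon with stop changes was 0.320 for RUNX1 (0.0411 simulated). The 3 BHLHE40 pairs gave 0.1004 to 0.124 (0.0363 simulated) and the MXD1 pairs gave 0.0603 to 0.0717 (0.0650 simulated). The MEF2C pairs (0.0179 to 0.0387) lay below the simulated 0.0622. The NCOA3 pairs gave 0.0438 to 0.0531 (0.0369 simulated) the MEIS1 pairs 0.0490 to 0.114 (0.0508 simulated) and the MEIS2 pair 0.0479 (0.0318 simulated).

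Between experiments of 1 scheme, RUNX1 and BHLHE40 loss shared 252 rising genes (99.7 by independent calls) and 120 falling genes (136.9). Another 383 genes moved in opposite directions (235.4), ISG15 and MX1 among them. NCOA3 and BHLHE40 loss shared 36 falling (4.25) and 9 rising genes (1.40). RUNX1 and NCOA3 loss shared 16 falling (8.77) and 12 rising genes (3.84). MXD1 and RUNX1 loss shared 1 rising gene, RRS1, and moved 10 genes in opposite directions (2.29). No gene was called in 1 direction in all 4 PrS experiments. HIVEP1, PPP1R18, SLC16A5, SLC35E3 and TMEM37 rose in 3 of them. AGFG2, COL21A1, ENSG00000284691, LAP3, LPIN2, OSMR, PRRT1B, SLC39A14 and ZNF114 fell in 3. Summed over all pairs, which counts a gene once per pair, 451 calls were shared.

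Within 500 kb of an altered locus 7 of 101 tests of neighbours were called (6.93%), against 3.97% of other tests (Fisher's exact p = 0.124). RCAN1 fell (-0.85 and -0.79) and CLIC6 rose (1.01 and 0.91) after RUNX1 exon deletion and premature stop. ARL8B (0.45), EDEM1 (0.48) and ITPR1 (0.74) rose after BHLHE40 full deletion (3 of 7 tested, 0 of 7 in exon or stop). Within 100 kb 0 of 26 were called.

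**Figure D5:**
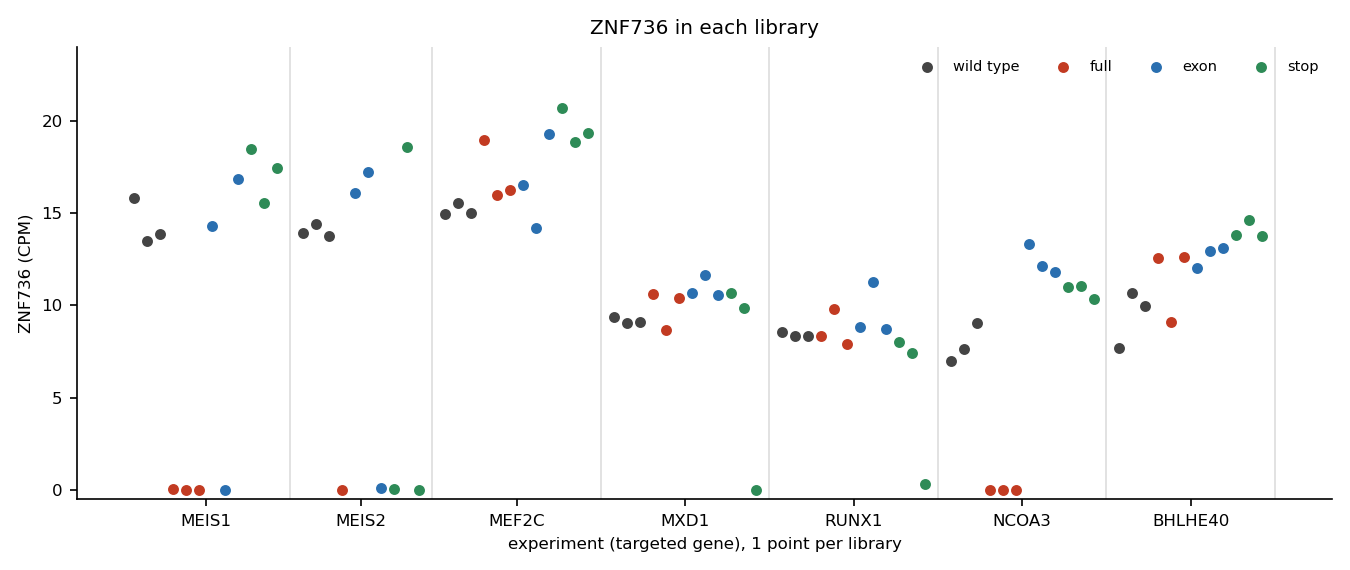
Level of ZNF736 in every library of the 7 experiments (CPM) by group. It is at or near 0 in all NCOA3 full and all MEIS1 full libraries and in some clones of other groups, and is expressed in all wild-type libraries.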

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

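Tests chosen only after the result was seen were those on a share of syncytiotrophoblast-like cells, on the sequencing lane, on damage around the edited locus, on loss of the segment around off genes other than ZNF736 and on silencing whichever gene was edited.

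Differences between groups drew attention to the strategies, whose effects on the same gene differed by a joint edgeR test. They differed for 5 genes in the MEIS2 experiment, 1 in MXD1, 2289 in RUNX1, 2 in NCOA3 and 5 in BHLHE40. The targeted gene itself differed for MXD1 (adjusted p = 0.000105), RUNX1 (4.91e-07), NCOA3 (0.038) and BHLHE40 (1.93e-14). Signals in data outside the comparisons were the multimapping share of MXD1 full libraries 1 and 2 (9.928% and 11.925%) and of BHLHE40 stop libraries 1 and 2 (22.752% and 26.683%), and the level of MEIS2 in the single library labelled full deletion (23.74 CPM), which lay above its wild types.

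In the RUNX1 experiment knockout and wild-type libraries parted on genes such as TPM2 and MYL9. Depth as the cause was argued against, since 4 of the 9 knockout libraries lay inside the range of counts of the wild-type libraries. A library state that clones of other experiments also show is a candidate explanation: with a score for it, built from the spread within groups of the MXD1 and NCOA3 experiments, 1.071% of the 4761 genes called stayed called, the median size of their change fell from 0.5535 to 0.2353 log2 units and its SE rose from 0.1326 to 0.1734, so calls ended through both. Wild-type libraries scored 14.47 ± 5.971 and knockout libraries -4.822 ± 11.4 (two-sided exact permutation p = 0.02273, n = 3 and 9), while in the BHLHE40 experiment 45.95% of 1937 genes stayed called. It stays open whether the score follows from the loss of RUNX1 itself, which the design cannot part from it. The share of unmapped reads, which parted the groups without overlap, was not tested as a cause.

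Syncytiotrophoblast genes varied within groups of the MEIS1 and MEF2C experiments. The sequencing lane as the whole cause was argued against, since the MEF2C libraries, all in 1 lane, spanned 2.1025 log2 units in the list mean. A varying share of syncytiotrophoblast-like cells stays open, because deviations of that list and of the mesenchyme list correlated at r = -0.0571 in MEIS1 (permutation p = 0.8819, adjusted 0.8819, rho = -0.042, permutation p = 0.9182, adjusted 0.9367, r = -0.0728 without the 2 farthest libraries) but at r = -0.8804 in MEF2C (permutation p = 0.0008, adjusted 0.0046, rho = -0.9091, permutation p = 0.0008, adjusted 0.0046, r = -0.8927), among 6 relations over 12 libraries each. The multimapping share gave r = 0.2207 in MEIS1 (permutation p = 0.6744, adjusted 0.8093, rho = 0.035, permutation p = 0.9367, adjusted 0.9367, r = 0.5017 without the 2 farthest) and r = 0.7127 in MEF2C (permutation p = 0.01, adjusted 0.0301, rho = 0.7552, permutation p = 0.017, adjusted 0.0509, r = 0.6363). By the bound set beforehand (a size under 0.3 in either experiment) the value 0.2207 argued against multimapping, but that reading was relaxed to open after the value was seen, because over 12 libraries it moved to 0.5017 without 2 of them and so was not under the bound by more than its spread.

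Genes expressed in wild type were off in single clones, below 0.05 of the lowest wild-type library of their experiment: 45 such calls in 15 genes, in 27 of 61 knockout libraries (38 in 9 genes without MEIS1 stop library 2, which had the lowest syncytiotrophoblast list mean), and in 0 of 21 wild-type libraries set in the same way against the other wild types of their experiment, ZNF736 alone in 13 clones. Damage around the edited locus was argued against, since, the targeted gene left out, 0% of these calls lay on the chromosome of the edited gene. Loss of most of a segment of 1 Mb to each side was argued against too, since neighbours of ZNF736 had a median log2 ratio to wild type of -0.0452 in the clones where it was off, and of the 31 other calls with at least 3 neighbours 0% had a median under -1 (-0.2766 to 0.1464). Silencing that arises whichever gene was edited is a candidate explanation, as ZNF736 was off in clones of 5 experiments, while a smaller regional event stays open for NLRP7 and NLRP2, which overlap on chromosome 19 and were off together in 4 clones, NLRP2 being the lowest neighbour of NLRP7 (-3.2651 to -3.1194) in 5 more. Whether clones share a derivation is not given in the labels and stays open, and no explanation beyond those named here was tested.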

How the results depend on the processing

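Tests chosen only after the data were seen were those without both MXD1 full or both BHLHE40 stop libraries of high multimapping, the MEIS1 lists without wild-type library 1, the NCOA3 stop taken at the critical exon, and the library score.

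Of the counts recomputed under an alternative, 261 stayed within 1.5 times the reported count and 213 moved further. Of the changes of targeted genes 151 kept their direction and side of the threshold, 7 newly passed and 2 no longer passed, and of those of named genes 3453 kept both, 331 no longer passed, 32 newly passed and 55 reversed. The reversed ones belong to 16 changes that were not called in the report. Unless stated, the cause was not tested.

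Ranges are those with each library or experiment left out in turn. In the MEF2C experiment MEF2D (-0.0083) became 0.0059 with RLE size factors, 0.0065 without a filter, 0.0058 with DESeq2 and -0.1046 to 0.0873. In MEIS1, TGIF2 (-0.0085) became 0.0016 without a filter and -0.0533 to 0.0272, and PKNOX2 (0.0355) -0.2029 to 0.2236. In MEIS2, TGIF2 (0.0332) became -0.0030 to 0.0688, PKNOX1 (0.0099) -0.0269 with the full library averaged in and -0.0413 to 0.0529, and TGIF1 (-0.0026) 0.0096 with Salmon estimates, 0.0188 with the full library averaged in and -0.0181 to 0.0067. In MXD1, MNT (-0.0553) became -0.1197 to 0.0016, MLX (0.0243) -0.0398 to 0.0885, MYC (0.0245) -0.0786 to 0.1584 and MGA (-0.0279) -0.0606 to 0.0047. MXD3 (0.0445) became -0.0739 without both full libraries and -0.0069 to 0.1237, and MXI1 (-0.1320) 0.0142 and -0.3371 to -0.0143. In NCOA3, NCOA1 (-0.0156) became 0.0004 without a filter and -0.0996 to 0.0442, and NCOA4 (0.0381) -0.0674 to 0.1785. Between wild types MEIS1 (0.0603) became -1.3043 within lane 3 (called) and -0.1641 to 0.2836, and RUNX1 (-0.5965) 0.0916 within lane 3 and -0.8406 to -0.3058. The medians of uncalled lists that changed sign with RLE or DESeq2 were those of neural ectoderm (-0.0036 to 0.0113) and the RUNX family (-0.0197 to 0.0095) in MEF2C and of cholesterol synthesis in MXD1 (0.0023 to -0.0035) and RUNX1 (-0.0096 to 0.0237). The MEIS1 syncytiotrophoblast list, lower and uncalled (0.854), was called higher (0.000285) without wild-type library 1.

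With DESeq2 in place of edgeR, MEIS1 gave 95 calls in place of 7, and 64, 24 and 39 for full, exon and stop and 1 between strategies in place of 0. MEIS2 gave 143 in place of 75, 25 in place of 10 for exon and 125 in place of 5 between strategies. MEF2C gave 1, 2 for full and 4 between strategies in place of 0. MXD1 gave 120 in place of 19, 199 in place of 9 for full, 61 in place of 2 for exon, 64 in place of 5 for stop and 95 in place of 1 between strategies. RUNX1 gave 1283 in place of 447 for full and 3528 in place of 2289 between strategies. NCOA3 gave 375 in place of 101, 383 in place of 92 for full, 433 in place of 73 for exon, 21 in place of 0 for stop and 11 in place of 2 between strategies. BHLHE40 gave 74 in place of 5 between strategies. DESeq2 also called the targeted gene in MEIS1 exon (-1.61) and stop (-2.02), MEF2C full (-4.02), MXD1 exon (-1.63) and stop (-1.64) and NCOA3 stop (-0.56). The median of all genes shifted by at most 0.0351 log2 units. RLE size factors gave 4 calls in place of 7 in MEIS1, and 8 in place of 19 and, for exon, 1 in place of 2 in MXD1.

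Without a low-count filter MEIS1 gave 34 calls in place of 7, with 4, 3 and 3 for full, exon and stop in place of 0. MEIS2 gave 651 in place of 75, 302 in place of 10 for exon, 1004 in place of 264 for stop and 669 in place of 5 between strategies. MXD1 gave 22, 5 and 12 for full, exon and stop in place of 9, 2 and 5, RUNX1 1092 in place of 447 for full and 3790 in place of 2289 between strategies. NCOA3 gave 163 in place of 101, 252, 125 and 7 for full, exon and stop in place of 92, 73 and 0, and BHLHE40 716 in place of 5 between strategies. Salmon estimates gave 34 in place of 75 and, for stop, 133 in place of 264 in MEIS2, 2 in place of 5 between strategies in BHLHE40 and 3 lists in place of 1 in NCOA3. A fit of only the 2 groups compared gave 1 in place of 0 for MEIS1 full, 190 in place of 10 and 161 in place of 264 for MEIS2 exon and stop, 2 in place of 0 for MEF2C full, 27 in place of 9 and 0 in place of 2 for MXD1 full and exon, 151 in place of 447 for RUNX1 full, 3 in place of 92 and 4 in place of 0 for NCOA3 full and stop, and 1880 in place of 1154 for BHLHE40 full. Averaging in the single MEIS2 full library gave 346 in place of 75.

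Camera with an estimated correlation called 0 lists in each of the 7 experiments and between wild types, in place of 14 in MEIS1, 14 in MEIS2, 10 in MEF2C, 9 in MXD1, 13 in RUNX1, 1 in NCOA3, 7 in BHLHE40 and 17 between wild types. Fry called 1 in MEIS1, 4 in RUNX1, 4 in BHLHE40 and 0 in MEIS2, MEF2C, MXD1 and NCOA3, and 22 between wild types. At an adjusted p of 0.01 experiments shared 148 calls in place of 451, and within 100 kb 0 neighbouring genes were called in place of 7, both since fewer genes enter. Over called genes alone the median correlation between strategies was 0.9041 in place of 0.5577, which calling genes against the same wild types raises by itself. Without both MXD1 full libraries the joint, full, exon, stop and differing counts were 2, 2, 1, 1 and 0, and without both BHLHE40 stop libraries 52 genes differed in place of 5; both leave 1 library in that group, assumed to vary like the other groups. With the library score as a covariate 59 genes were called in RUNX1 and 1239 in BHLHE40.

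Leaving out each library in turn gave these ranges. MEIS1 gave 2 to 14 calls, with 0 to 2 for exon, 0 to 1 for stop and 0 to 1 between strategies. MEIS2 gave 14 to 280, 2 to 13 for exon, 22 to 797 for stop and 0 to 455 between strategies. MXD1 gave 2 to 30, 2 to 1076 for full, 0 to 5 for exon, 0 to 5 for stop, 1 to 1027 between strategies, and -2.01 to -1.39 for the change of MXD1 in stop clones, which newly passed without stop library 1 (adjusted p = 0.0252). RUNX1 gave 1395 to 6585, 16 to 2010 for full, 2100 to 3568 for exon, 2871 to 5074 for stop and 458 to 4695 between strategies. NCOA3 gave 3 to 341, 4 to 1477 for full, 1 to 36 for exon and 1 to 442 between strategies. BHLHE40 gave 1185 to 2693, 661 to 924 for full, 992 to 3128 for stop, 4 to 848 between strategies, and 0.45 to 0.58 for the change of BHLHE40 in exon clones, which no longer passed without exon library 2 or wild-type library 2. These fits hold fewer libraries, and their spread was pooled over groups.

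Between wild types, taking all 21 libraries as samples gave 14359 calls, and 14166 with the replicate number as a block, in place of 11469. The numbers do not pair libraries: the correlation of same-number libraries exceeded 0.1 in 4 of 63 pairs (median 0.014), and 10 of 21 libraries were closest to their own number. Depth sets the limit of a count of 0. The recovery of planted 1.5-fold changes did not follow depth: it was 6% in MEF2C, 59.7% in NCOA3, at overlapping depths, and 3% between wild types, against 83.3%, 98.5% and 56.1% of planted 4-fold changes.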

Other observations

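Tests chosen only after the result was seen were the splits of the MXD1 full, exon and stop comparisons and of the wild types.

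Other splits of the libraries were fitted to see how often they call as many genes. Of 60 splits, 2 gave as many genes as the real MEIS1 knockout comparison (7, highest other 825), and 1, the real split, as many as MEIS2 (75, highest other 43), MXD1 (19, 12), RUNX1 (4761, 2370), NCOA3 (101, 1) and BHLHE40 (1937, 324). Chance was thereby excluded for these 6. For MEF2C (0, highest other 4234) the count of 0 means that 60 of 60 had to give as many, so the splits decide nothing. Of the 35 splits of the wild types 1, the real split, gave as many genes (11469, highest other 0), a share under 0.05. For the test between strategies 2 of 60 splits gave as many in RUNX1 (2289, highest other 3323), a share under 0.05. In MXD1 6 did (1, 1544), in NCOA3 4 (2, 2460) and in BHLHE40 8 (5, 519), shares over 0.05. Chance stays open for RUNX1 too, as another split called more and the count became 458 without full library 2. The counts of 0 in MEIS1 (60 splits, highest other 5) and MEF2C (60, 8417) again decide nothing.

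For each single strategy, and for the MEIS2 test between strategies, only 10 splits exist, too few for a share under 0.05. In MEIS1 10 splits gave as many as full (0, highest other 2), exon (0, 0) and stop (0, 0). In MEIS2 1 gave as many as exon (10, 1), stop (264, 0) and the difference between strategies (5, 1). In MEF2C 10 gave as many as each strategy (0, 0), and in MXD1 1 as many as full (9, 0), exon (2, 0) and stop (5, 0). In RUNX1 1 gave as many as full (447, 201), exon (4322, 0) and stop (5915, 0). In NCOA3 2 gave as many as full (92, 1250), 1 as exon (73, 0) and 10 as stop (0, 0). In BHLHE40 1 gave as many as full (1154, 0), exon (1054, 0) and stop (1856, 0). Some splits called over 5 times the real count, or over 5 genes where that was 0, namely 1 for MEIS1, 2 for MEF2C and 1 for NCOA3 full, and between strategies 2 for MEF2C, 4 for MXD1, 2 for NCOA3 and 3 for BHLHE40. These point to a structure of the samples that the groups do not follow.

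Besides ZNF736, NLRP7 was off in 10 clones of 3 experiments, NLRP2 in 4 clones of 2, CHCHD2 in 3 of 3, SDR42E1 in 3 of 2, H4C13 in 2 of 2 and TNFSF10 in 2 of 1. The hormone subunit gene CGA had 0 counts in MEIS1 stop library 2, where up to 3 counts (0.1316 CPM) would go unseen, against 127.4983 CPM in the lowest wild-type library, at least 968.6-fold lower. That library also had the lowest syncytiotrophoblast list mean of the MEIS1 experiment (-2.4937), with CYP19A1 and ERVW-1 off too. The mitochondrial share and the syncytiotrophoblast list mean correlated within groups at r = -0.5722 in MEIS1 (permutation p = 0.1597, adjusted 0.3194, rho = -0.5944, permutation p = 0.1173, adjusted 0.2346, r = -0.6893 without the 2 farthest libraries). In MEF2C they gave r = 0.2823 (permutation p = 0.5123, adjusted 0.7685, rho = 0.1538, permutation p = 0.7153, adjusted 0.9367, r = 0.0135 without the 2 farthest).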
